A study of Bos taurus with 16 samples.

How the data were processed

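RNA sequencing of bovine (Bos taurus) trophoblast stem cells was deposited as tables of 16 libraries. Per the labels, the cells came from bovine blastocysts, were grown with or without feeders, and were treated with TGFB1 at 10 ng/ml or with the ROCK inhibitor Y-27632 at 10 µM. Total RNA was isolated with an RNAqueous Micro kit, mRNA was captured by poly(A), and libraries were made with a TruSeq stranded kit. The submitters' processing notes name FastQC, TopHat and edgeR, with no versions, and the counting tool, genome build and annotation are not given in the sources used here. Genes are identified by symbol, without coordinates.

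The values in the deposited count table are expected counts per gene, that is estimated counts not scaled to the library total; 137 of 13897 genes held fractions, and values were rounded to whole counts for the fits. The second deposited table holds FPKM, computed by the authors with gene lengths and totals that are not stated. For 96.4% of 7971 compared genes the ratio of count to FPKM, after a constant per library, varied with a coefficient of variation under 1%. Among the counted genes, 1729 had no count in any library and 24 had names turned into dates, whose symbols were not restored. Totals ran from 15407105 to 22709408 counts per library. The floor for a gene at 0 in a whole group was set at 3 counts per library, which covers counting error only. Library duplicates were checked: every pair within a group differed by a chi-square per degree of freedom of at least 6.06.

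Counts were analysed in R 4.3.3 with edgeR 4.0.16 (filterByExpr on the 4 groups, TMM factors, glmQLFit and glmQLFTest), all 16 libraries in 1 fit, with Benjamini-Hochberg adjustment over 9808 genes and a threshold of 0.05. The comparisons were TGFB1 against Rocki, TGFB1+Rocki against Rocki, TGFB1+Rocki against TGFB1 and FF-Rocki against Rocki. Tests are two-sided. In 25 gene lists fixed before the data were examined, members were counted over all genes and adjusted over the list alone, and camera (limma 3.58.1) was run with a preset correlation of 0.01 and again with an estimated correlation. Of 96 list tests 40 passed with the preset correlation, 0 with the estimated one and 39 of the 40 with fry, and the list median, mean and test differed in sign in 17 tests, none of them past the threshold. The list of mitochondrially encoded genes had no gene in the file. The other lists were core trophoblast, secreted and binucleate, steroid and prostaglandin, TGFB and SMAD, BMP and ID, actin and SRF, YAP and TEAD, Rho and ROCK, epithelial junction, mesenchymal, extracellular matrix, fibroblast, endothelial and leukocyte, epiblast, hypoblast, cell cycle, interferon response, immediate early and stress, p53, hypoxia and glycolysis, cholesterol and lipid, imprinted, WNT and sex-linked genes.

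Named genes followed a rule set before the data were examined. They were the 5 largest log2 fold changes in each direction among genes past the threshold with a symbol, at least 5 CPM in the higher group and no overlap between groups; up to 4 members of each list with the smallest adjusted p, of which fewer are printed; and SERPINE1, SMAD7, TAGLN, ACTA2, VIM, CDH1, CDX2, GATA3, ELF5, KRT8, an interferon tau gene, PAG2, CSH2 and XIST whatever their result. Genes listed at 0 in a whole group with a median of at least 1000 counts in another are given apart. OFD1Y, HAND1 and the genes of single libraries in the closing section were chosen after their values were seen.

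The fit was tested on simulated data with known changes. At 1.5-, 2- and 4-fold, 46.3%, 86.6% and 100% of changed genes were recovered for TGFB1 against Rocki, 26.9%, 77.6% and 98.5% for TGFB1+Rocki against Rocki, 28.4%, 80.6% and 98.5% for TGFB1+Rocki against TGFB1, and 47.8%, 82.1% and 100% for FF-Rocki against Rocki. Unchanged genes made up 0 of 155, 1 of 136, 1 of 139 and 32 of 185 calls. The last share exceeds 5%, and its cause was not tested.

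Alternatives were DESeq2 1.42.0 size factors and its Wald test, library totals without TMM, no filter beyond 1 read, at least 10 reads in 3 libraries, the 2 groups alone, the replicate number as a block, each library left out in turn, an absolute log2 fold change of at least 1, limma-trend on log2 of FPKM + 1 for genes with a mean FPKM of at least 1, and robust empirical Bayes. In the replicate block FF-Rocki 5 was the only library of its number, so it was fitted exactly and did not bear on the group differences. Fits without the FF-Rocki libraries, without the genes listed at 0, and with limma-voom and a variance per group were added after seeing the data. Every split of the libraries into groups of the same sizes, or 100 drawn splits, was fitted for the 2 groups alone.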

Results

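Bovine trophoblast stem cells, cultured from the trophectoderm of blastocysts made by in vitro fertilisation, were profiled by RNA sequencing in 16 libraries. The 4 groups were cells with the ROCK inhibitor Y-27632 (Rocki, n = 4), cells with TGFB1 (TGFB1, n = 4), cells with both (TGFB1+Rocki, n = 3) and a further inhibitor group that the labels call FF-Rocki (n = 5). Y-27632 blocks the Rho-associated kinases that drive actomyosin contraction, and TGFB1 is a growth factor that signals through SMAD2 and SMAD3. No group was left untreated, and the labels do not spell out FF. Library totals ran from 17513072 to 20428198 counts in Rocki, 18383785 to 22709408 in TGFB1, 18776462 to 21640914 in TGFB1+Rocki and 15407105 to 19111847 in FF-Rocki. Levels below are TMM-scaled counts-per-million (CPM), given as mean ± SD over the libraries of a group, and fold changes are edgeR log2 estimates ± SE. The first principal component of the 9808 tested genes held 62.0% of the variance and separated FF-Rocki from the other groups. The mean correlation of log CPM within a group was 0.99 in Rocki, TGFB1 and TGFB1+Rocki and 0.960 in FF-Rocki, across genes, which are not independent replicates. The labels do not say whether the libraries of a group came from separate cultures or embryos, so the p values measure the spread between these libraries. That spread may be technical, except that the FF-Rocki libraries also differ in XIST and Y-linked genes, as given below.

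Between TGFB1 and Rocki both factors differed, since TGFB1 was added and the inhibitor was absent. ROBO4 and SPP1 rose in TGFB1, and CYP19A1 and PAG2 fell. ROBO4, a guidance receptor, was at 10.4 ± 1.69 CPM in TGFB1 and 0.0281 ± 0.0561 in Rocki, a log2 fold change of 8.29 ± 0.58 (edgeR adjusted p = 3.9e-07). SPP1, the matrix phosphoprotein osteopontin, was at 2063 ± 653 against 65.7 ± 18.3 CPM (4.97 ± 0.43). CYP19A1, the aromatase that makes oestrogens, was at 1.15 ± 0.166 against 64.9 ± 23.6 CPM (-5.81 ± 0.47, adjusted p = 1.2e-06). PAG2, a pregnancy-associated glycoprotein, was at 417 ± 106 against 5621 ± 1221 CPM (-3.75 ± 0.28). The other Rocki libraries than Rocki 2 had no count of ROBO4, so its fold is poorly bounded. Other large increases were in the chemokine CCL2 (6.90, or 7.79 without Rocki 4), the secreted protease HTRA1 (6.25) and the laminin chain LAMA4 (5.27). PAG12 (-5.68), the trophoblast Kunitz domain gene TKDP4 (-4.61) and GPLD1 (-3.79) fell. LYZ3, a lysozyme gene at 8.74 CPM in Rocki, had no count in TGFB1 and was at least 56.0-fold lower against a floor of 3 counts per library. In all, 2285 genes passed adjusted p 0.05, 1159 higher and 1126 lower, and 573 of them changed by at least 1 on the log2 scale (411 higher, 162 lower). The libraries of the 2 groups did not overlap in 97.9% of the called genes and in 41.9% of all tested genes, where chance gives 2.86%. Without TGFB1 1 the count was 1447 and without Rocki 1 it was 1494, whereas it was 4398 with the 2 groups fitted alone and 4260 without the FF-Rocki libraries, an alternative chosen after seeing the data.

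Among the lists fixed beforehand, 16 of 27 tested extracellular matrix genes rose in TGFB1 against Rocki and none fell, or 20 adjusted over the list alone (camera adjusted p = 3.4e-10; adjusted p = 0.066 with an estimated correlation). LAMB3 (log2 fold change 2.53), COL12A1 (0.86) and the protease inhibitor TIMP1 (0.78) were among them. Of 29 TGFB and SMAD targets, 19 rose and 1 fell, or 21 and 2 adjusted over the list alone (camera adjusted p = 3.4e-10; adjusted p = 0.066 with an estimated correlation). SERPINE1, which encodes the plasminogen activator inhibitor PAI-1, was at 2264 ± 160 against 910 ± 69.5 CPM (1.31 ± 0.29, adjusted p = 0.0046). SMAD7, an inhibitor of the pathway, rose by 1.11 ± 0.23 (adjusted p = 0.0026), TGFB1 itself by 1.43, PMEPA1 by 2.06, LTBP1 by 1.09 and TGIF1 by 0.64. Of 30 actin genes and SRF targets, 16 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 5.4e-06; adjusted p = 0.13 with an estimated correlation). The actin-binding gene TAGLN was at 1066 ± 157 against 187 ± 74.8 CPM (2.51 ± 0.31), while ACTA2 stayed near 1 CPM (0.51 ± 0.40, adjusted p = 0.38). Of 16 YAP and TEAD targets, 6 rose, or 7 adjusted over the list alone, with ANKRD1 (2.40), NUAK2 (1.27) and CYR61 (0.98) as examples (camera adjusted p = 7.5e-04; adjusted p = 0.17 with an estimated correlation). The GTPase RND1, which opposes Rho signalling, rose by 3.02 ± 0.29, but the list of 26 Rho and ROCK pathway genes, with 7 higher and 2 lower, did not pass (camera adjusted p = 0.16).

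The immediate early and stress list had 14 of 30 members higher in TGFB1 than in Rocki, among them IER3 (log2 fold change 1.13) and the ERK phosphatase DUSP6 (1.45), or 19 adjusted over the list alone (camera adjusted p = 2.7e-07; adjusted p = 0.17 with an estimated correlation). That count was 9 without Rocki 1, Rocki 2, Rocki 3 or TGFB1 1. Of 33 cell cycle genes 16 fell and none rose, or 20 adjusted over the list alone (camera adjusted p = 6.6e-06; adjusted p = 0.17 with an estimated correlation), and 8 fell without TGFB1 1. The epithelial junction list had 12 of 33 members higher, including CLDN6 (0.49), or 14 higher and 1 lower adjusted over the list alone (camera adjusted p = 7.5e-04; adjusted p = 0.17 with an estimated correlation). The epithelial cadherin gene CDH1 was at 1508 ± 39.3 against 1454 ± 22.6 CPM (adjusted p = 0.61). In the mesenchymal list 11 of 26 members were higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 5.8e-04; adjusted p = 0.13 with an estimated correlation). The lower member was FN1, listed at 0 in TGFB1, and VIM was at 14.7 ± 2.66 against 12.3 ± 3.28 CPM (adjusted p = 0.39). WNT targets had 6 of 12 members higher, with WNT11 up by 1.48, or 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0030; adjusted p = 0.17 with an estimated correlation). In the p53, senescence and apoptosis list 7 of 20 were higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.014; adjusted p = 0.17 with an estimated correlation).

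Trophoblast genes moved in both directions in TGFB1 against Rocki. Of 21 core trophoblast genes 11 rose and 2 fell, or 11 and 4 adjusted over the list alone (camera adjusted p = 0.014; adjusted p = 0.17 with an estimated correlation), and 7 rose without Rocki 1. The keratin KRT7 (log2 fold change 1.65) and ID2 (1.32) rose. KRT8 (0.41, adjusted p = 0.044) and GATA3 (-0.45, adjusted p = 0.043) passed narrowly. KRT8 did not pass without Rocki 1, Rocki 2, Rocki 3 or any of the 4 TGFB1 libraries, nor GATA3 without Rocki 2, Rocki 3, Rocki 4 or any of the 4 TGFB1 libraries; their adjusted p then ran up to 0.14. CDX2, a trophectoderm transcription factor, was at 12.5 ± 0.985 against 11.5 ± 1.54 CPM (adjusted p = 0.81), and ELF5 at 0.977 ± 0.17 against 2.15 ± 0.65 CPM (-1.14, adjusted p = 0.053). ELF5 passed in 7 alternative settings, with adjusted p from 0.0040 with the 2 groups alone to 0.047 without Rocki 2. Of 14 tested genes for secreted and binucleate cell products, 7 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 7.8e-04; adjusted p = 0.13 with an estimated correlation). The riser was PAG11, listed at 0 in Rocki, and the call was lost without the FF-Rocki libraries (camera adjusted p = 0.24). Of 20 steroid and prostaglandin genes 5 fell and 4 rose, also when adjusted over the list alone (camera adjusted p = 0.019; adjusted p = 0.13 with an estimated correlation). SULT1E1 (-1.94), AKR1B1 (-1.16) and the prostaglandin transporter gene SLCO2A1 (-1.90) fell. The list call was lost with the 2 groups alone (camera adjusted p = 0.24), with the replicate block (0.31) and without the FF-Rocki libraries (0.19). IFNT3, an interferon tau gene, was near the floor at 0.672 ± 0.415 and 1.16 ± 0.469 CPM. XIST was at 563 ± 82.1 and 558 ± 91.4 CPM, and CSH2 was not among the tested genes. The other 10 lists did not pass, with camera adjusted p of 0.089 for BMP and ID targets, 0.16 for endothelial and leukocyte markers, 0.40 for hypoxia and glycolysis, 0.42 for epiblast, 0.50 for hypoblast, 0.52 for imprinted, 0.61 for interferon response, 0.73 for sex-linked, 0.93 for fibroblast and 0.93 for cholesterol and lipid genes. PAG, TKDP and IFNT are families of similar genes that can share reads, so values of single members are uncertain.

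**Figure D1:**
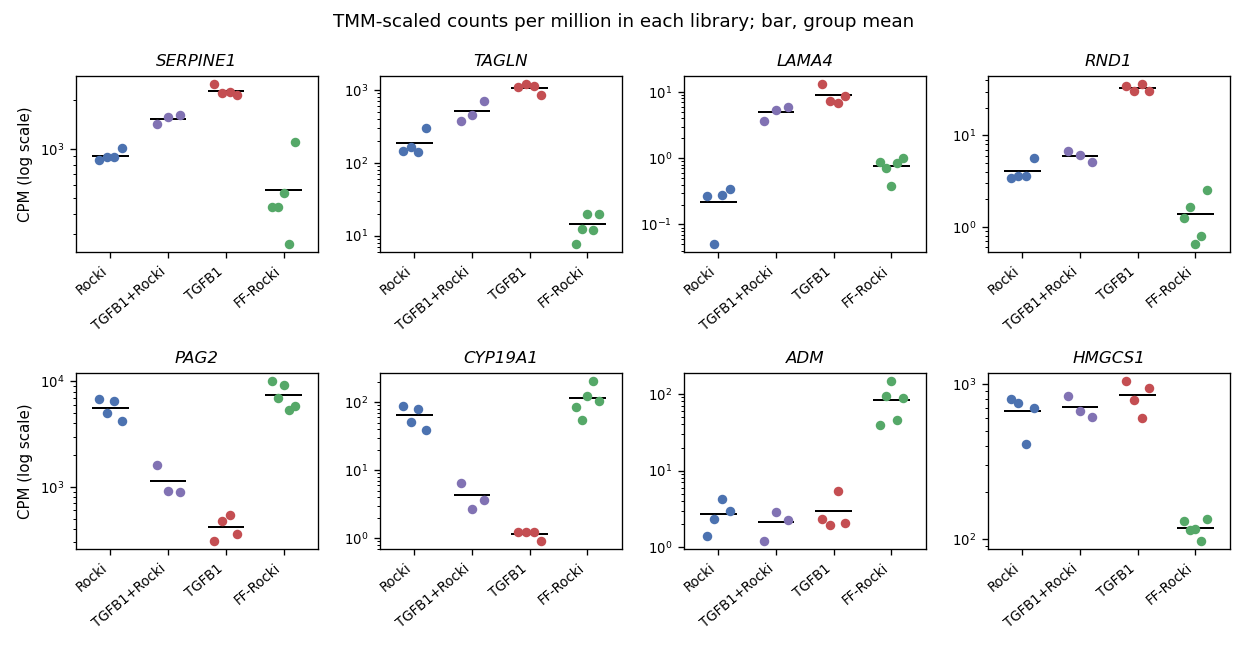
TMM-scaled counts-per-million of 8 genes on log axes, with a point per library and a bar at the group mean, for Rocki, TGFB1+Rocki, TGFB1 and FF-Rocki. SERPINE1, TAGLN, LAMA4 and RND1 had higher means in TGFB1 than in Rocki (RND1 33.1 against 4.06 CPM), PAG2 and CYP19A1 lower means, and ADM and HMGCS1 stood apart in FF-Rocki (ADM 83.3 against 2.73 CPM in Rocki).

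With the inhibitor present in both groups, HTRA1, LAMA4 and SPP1 were higher and CYP19A1, PAG2 and PAG12 lower in cells with TGFB1 than in cells without it. HTRA1 was at 6.79 ± 0.679 CPM in TGFB1+Rocki and 0.107 ± 0.0919 in Rocki (log2 fold change 5.90 ± 0.62, adjusted p = 6.4e-05). LAMA4 rose by 4.44 ± 0.46 and SPP1 by 3.40 ± 0.41, the proton pump subunit gene ATP6V1B1 by 3.17 and CRCT1 by 3.08, the last lost with the DESeq2 Wald test (adjusted p = 0.058). CYP19A1 was at 4.26 ± 1.94 against 64.9 ± 23.6 CPM (-3.94 ± 0.45, adjusted p = 1.3e-04) and PAG2 at 1136 ± 406 against 5621 ± 1221 CPM (-2.31 ± 0.29). LYZ3 (-7.28), PAG12 (-4.91), TKDP4 (-3.38) and the cytokine IL33 (-2.98) were also lower. Without TGFB1+Rocki 1 PAG12 was at -6.14 and TKDP4 at -3.997. LYZ3 was at -6.61 without Rocki 1, and TGFB1+Rocki 2 and 3 had no count of it, so its fold is poorly bounded. In all, 378 genes passed, 207 higher and 171 lower, and 153 changed by at least 1 on the log2 scale (92 higher, 61 lower). The libraries did not overlap in 98.9% of the called genes and in 25.8% of all tested genes, where chance gives 5.71%. The count was 155 without Rocki 1, 176 without Rocki 2, 160 without Rocki 3, 122 without TGFB1+Rocki 2 and 100 without TGFB1+Rocki 3, whereas it was 1314 with the 2 groups alone, 673 with the DESeq2 Wald test and 1932 without the FF-Rocki libraries.

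Of 29 TGFB and SMAD targets, 7 rose in TGFB1+Rocki against Rocki, or 16 adjusted over the list alone (camera adjusted p = 2.0e-08; adjusted p = 0.10 with an estimated correlation). PMEPA1 (log2 fold change 1.93), RHOB (0.64), TGFB1 (0.86), LTBP2 (1.91) and SMAD7 (0.92, adjusted p = 0.044) were among the called genes, and SERPINE1 was at 1534 ± 98.6 against 910 ± 69.5 CPM (0.75 ± 0.31, adjusted p = 0.20, but from 6.4e-05 to 0.023 in 4 alternative settings). Extracellular matrix genes had 5 of 27 members higher, with COL12A1 (1.00) and LAMB3 (1.71), or 10 adjusted over the list alone (camera adjusted p = 2.0e-08; adjusted p = 0.10 with an estimated correlation). Of 30 actin genes and SRF targets 3 rose, including ZYX (0.95) and TAGLN (1.44, adjusted p = 0.019), or 8 with 1 lower adjusted over the list alone (camera adjusted p = 4.5e-04; adjusted p = 0.29 with an estimated correlation). YAP and TEAD targets had 2 of 16 higher, including NUAK2 (0.65), or 7 adjusted over the list alone (camera adjusted p = 0.0029; adjusted p = 0.31 with an estimated correlation). WNT targets had 3 of 12 higher, with WNT11 (1.39) and the cyclin gene CCND1 (1.28), or 5 adjusted over the list alone (camera adjusted p = 1.2e-05; adjusted p = 0.14 with an estimated correlation). Several of these calls were lost when a library was left out, whichever of several it was. LTBP2, LAMB3, TAGLN and NUAK2 did not pass without Rocki 1, Rocki 2, Rocki 3, TGFB1+Rocki 2 or TGFB1+Rocki 3, with log2 fold changes of 1.73 to 1.91, 1.498 to 1.697, 1.13 to 1.53 and 0.57 to 0.65 there. SMAD7 did not pass when any of the 7 libraries was left out (0.88 to 0.98), TGFB1 did not without TGFB1+Rocki 3 (adjusted p = 0.065) and CCND1 did not without TGFB1+Rocki 2 (0.056). The TGFB and SMAD count was 3 without Rocki 1, Rocki 2, Rocki 3 or TGFB1+Rocki 2 and 2 without TGFB1+Rocki 3, and the YAP and TEAD count was 0 without any of these 5 and 1 without Rocki 4. The matrix count was 3 without Rocki 3 and 2 without Rocki 1, Rocki 2, TGFB1+Rocki 2 or TGFB1+Rocki 3, the actin count was 1 without Rocki 1, TGFB1+Rocki 2 or TGFB1+Rocki 3, and the WNT count was 1 without TGFB1+Rocki 2. All these fits kept the FF-Rocki libraries, and the log2 fold changes of the named genes kept their direction in them. Leaving out a library in a fit without FF-Rocki was not tried. With the replicate block the TGFB and SMAD, actin, WNT, and YAP and TEAD counts were higher, at 15, 9, 8 and 4.

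The core trophoblast list had 3 of 21 members higher and 1 lower in TGFB1+Rocki against Rocki, or 8 and 3 adjusted over the list alone (camera adjusted p = 0.039; adjusted p = 0.38 with an estimated correlation). KRT7 (log2 fold change 0.90) was called, but it and each other rising member did not pass without Rocki 1, Rocki 2, Rocki 3, TGFB1+Rocki 2 or TGFB1+Rocki 3, where the count was 0. CDX2 was at 14.4 ± 0.912 against 11.5 ± 1.54 CPM (adjusted p = 0.60), GATA3 at 172 ± 20.3 against 213 ± 30.6 (adjusted p = 0.32), KRT8 at 869 ± 85.8 against 669 ± 86 (adjusted p = 0.19) and ELF5 at 0.676 ± 0.331 against 2.15 ± 0.65 (-1.68, adjusted p = 0.055). ELF5 passed in 7 alternative settings (adjusted p from 0.0046 without the FF-Rocki libraries to 0.048 with library totals) and KRT8 in 4 (0.018 without the FF-Rocki libraries to 0.043 with the replicate block). CDX2 passed without the FF-Rocki libraries (0.0496) and GATA3 with the replicate block (0.041). Of 20 steroid and prostaglandin genes 4 fell, with SULT1E1 (-1.97) and AKR1B1 (-0.80), or 4 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.0082; adjusted p = 0.10 with an estimated correlation). Without TGFB1+Rocki 3 AKR1B1 did not pass (adjusted p = 0.062) and 2 members fell. The list call was lost with the replicate block (camera adjusted p = 0.096), without the FF-Rocki libraries (0.069) and with the 2 groups alone (0.054). The mesenchymal list had 4 of 26 higher, with ITGA5 (1.93) and the gelatinase gene MMP9 (2.69), and 1 lower, FN1, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.013; adjusted p = 0.31 with an estimated correlation). Without TGFB1+Rocki 3 it had 2 higher. Its call was lost with the 2 groups alone and without the FF-Rocki libraries (camera adjusted p = 0.085 in both). In the immediate early and stress list 1 of 30 rose, also when adjusted over the list alone, and 2 without Rocki 4 (camera adjusted p = 1.5e-05; adjusted p = 0.33 with an estimated correlation). ACTA2 (0.389 ± 0.205 against 0.772 ± 0.0859 CPM, adjusted p = 0.30), VIM (16.6 ± 3.24 against 12.3 ± 3.28, adjusted p = 0.32), CDH1 (1412 ± 100.4 against 1454 ± 22.6, adjusted p = 0.80) and XIST (432 ± 20.5 against 558 ± 91.4, adjusted p = 0.90) did not pass. IFNT3 was at 1.57 ± 1.5 against 1.16 ± 0.469 CPM (adjusted p = 0.93). Of 14 secreted and binucleate genes 5 fell and 2 rose, also when adjusted over the list alone, or 4 and 1 without PAG11, listed at 0 in Rocki, and TKDP1, listed at 0 in FF-Rocki. The list did not pass (camera adjusted p = 0.056; adjusted p = 0.31 with an estimated correlation). The other 14 lists gave camera adjusted p from 0.051, for cell cycle genes, to 0.93, for cholesterol and lipid genes.

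Most genes called in TGFB1+Rocki against Rocki were also called in TGFB1 against Rocki. In the latter the inhibitor differs as well, and both were measured against the same Rocki libraries. Of the 378 genes called in TGFB1+Rocki against Rocki, 365 were called in the same direction in TGFB1 against Rocki (199 higher, 166 lower) and none in the opposite one. The product of the 2 counts over the tested genes gives 24.5 higher and 19.6 lower. In 20 simulated data sets with no change between groups neither comparison had a call, so they give no expected shared count. The log2 fold changes correlated with r = 0.80 across genes, against 0.48 in the simulation from the shared libraries alone, and their covariance was 0.282 against 0.0259, a difference of 0.256. With the Rocki libraries split so that each comparison had its own, 117 genes were shared on average over 6 splits (65 to 198, of 131 called), with r = 0.65 and a covariance of 0.253. EEF1A1, PAG11, RN18S1 and RN45S were listed at 0 in Rocki and counted in both groups with TGFB1, and FN1 the reverse. Neither the simulation nor the split can separate TGFB1 from a difference in processing between Rocki and both these groups.

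With the inhibitor added to TGFB1, RND1, PLAU, CCL2 and ALOX12E were lower. RND1 was at 5.98 ± 0.855 CPM in TGFB1+Rocki and 33.1 ± 2.96 in TGFB1 (log2 fold change -2.47 ± 0.31, adjusted p = 0.0027). PLAU, the urokinase gene, was at 200.3 ± 19.7 against 756 ± 84.5 CPM (-1.92 ± 0.22, adjusted p = 0.0022), and CCL2 at 0.318 ± 0.159 against 5.56 ± 1.25 CPM (-4.11 ± 0.56). ALOX12E, a lipoxygenase gene, fell by 3.64 ± 0.49. PAG2 was higher, at 1136 ± 406 against 417 ± 106 CPM (1.45 ± 0.27, adjusted p = 0.021). Of 59 genes past the threshold 10 were higher and 49 lower, and 36 changed by at least 1 on the log2 scale (2 higher, 34 lower), while 973 had an unadjusted p under 0.05. The libraries did not overlap in any of the 59 and in 20.4% of all tested genes, where chance gives 5.71%. The count was 11, 10 and 18 without TGFB1+Rocki 1, 2 and 3, and 26, 38, 38 and 35 without TGFB1 1, 2, 3 and 4. It was 720 with the 2 groups alone, 200 with the DESeq2 Wald test and 892 without the FF-Rocki libraries.

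Of the genes named for TGFB1+Rocki against TGFB1, only CCL2, ALOX12E, RND1 and PLAU passed without each library in turn, in fits that kept the FF-Rocki libraries. With all FF-Rocki libraries left out 892 genes passed, among them all 59 of the main fit. Leaving out a further library there was not tried. The collagen genes COL4A3 (log2 fold change -2.64), COL6A1 (-2.53) and COL6A2 (-2.36), the integrin ITGA5 (-1.28), the cytokines IL1A (-1.28) and IL6 (-1.96) and LTBP1 (-0.72) were lower. UGT1A1 (1.90), LDOC1 (0.84), EPHX2 (0.78) and CDCA7 (0.78) were higher. Each of these 11 and PAG2 lost its call without TGFB1+Rocki 1, and all of them without TGFB1+Rocki 2. Without TGFB1+Rocki 3 COL4A3, COL6A1, COL6A2, ITGA5, IL1A, IL6 and LDOC1 did not pass, nor without TGFB1 1 COL4A3, COL6A1, COL6A2, ITGA5, IL6 and PAG2. COL6A1, COL6A2, IL6 and UGT1A1 did not pass without TGFB1 2 or TGFB1 3, nor IL6, UGT1A1 and PAG2 without TGFB1 4. SERPINE1 (1534 ± 98.6 against 2264 ± 160 CPM, adjusted p = 0.62) and TAGLN (509 ± 174 against 1066 ± 157 CPM, adjusted p = 0.19) did not pass, but did with the 2 groups alone (adjusted p = 0.0015 and 0.0088), as in 2 and 3 further settings. SMAD7 (adjusted p = 0.90), ACTA2 (0.23), VIM (0.91), CDH1 (0.78), CDX2 (0.92), GATA3 (0.90), ELF5 (0.83), KRT8 (0.99) and XIST (0.98) did not pass either, but ACTA2 did with the 2 groups alone (log2 fold change -1.51, adjusted p = 0.034) and without the FF-Rocki libraries (adjusted p = 0.013). IFNT3 was at 1.57 ± 1.5 against 0.672 ± 0.415 CPM.

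Camera ranked cell cycle genes upward in TGFB1+Rocki against TGFB1, although 0 of the 33 passed singly in edgeR, also when adjusted over the list alone (camera adjusted p = 5.7e-08; adjusted p = 0.15 with an estimated correlation); over all genes 973 had an unadjusted p under 0.05 and 200 passed with DESeq2. The secreted and binucleate list was also ranked upward, with 1 of 14 higher, PAG2, also when adjusted over the list alone (camera adjusted p = 4.0e-05; adjusted p = 0.11 with an estimated correlation). Lists ranked downward were the p53, senescence and apoptosis list with 2 of 20 lower, or 5 adjusted over the list alone (camera adjusted p = 3.8e-05; adjusted p = 0.11 with an estimated correlation), and the extracellular matrix with 3 of 27 lower, or 5 adjusted over the list alone (camera adjusted p = 4.0e-05; adjusted p = 0.15 with an estimated correlation). The TGFB and SMAD targets had 1 of 29 lower, LTBP1, or 6 lower and 1 higher adjusted over the list alone (camera adjusted p = 4.0e-05; adjusted p = 0.15 with an estimated correlation). The mesenchymal list had 2 of 26 lower, PLAU and ITGA5, or 5 adjusted over the list alone (camera adjusted p = 6.9e-04; adjusted p = 0.15 with an estimated correlation). Epithelial junction genes had 0 of 33 called, or 5 lower adjusted over the list alone (camera adjusted p = 3.8e-05; adjusted p = 0.15 with an estimated correlation). Actin genes and SRF targets had 0 of 30, or 4 lower adjusted over the list alone (camera adjusted p = 2.8e-04; adjusted p = 0.18 with an estimated correlation). Immediate early and stress genes had 0 of 30, or 3 lower adjusted over the list alone (camera adjusted p = 2.8e-04; adjusted p = 0.39 with an estimated correlation, and 0.24 with fry). The other 15 lists gave camera adjusted p from 0.053, for YAP and TEAD targets, to 0.75. The matrix and p53 counts were 0 without TGFB1+Rocki 1, TGFB1+Rocki 2 or TGFB1+Rocki 3, and the matrix count was also 0 without TGFB1 1 and 1 without TGFB1 2 or TGFB1 3. The p53 count was 1 without any of the 4 TGFB1 libraries, and the mesenchymal count was 1 without any TGFB1+Rocki library or TGFB1 1. The TGFB and SMAD count was 0 without TGFB1+Rocki 1 or TGFB1+Rocki 2, the secreted and binucleate count was 0 without these or TGFB1 1 or TGFB1 4, and the immediate early count was 1 without TGFB1 1. Each of these fits with a library left out kept the FF-Rocki libraries.

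**Figure D2:**
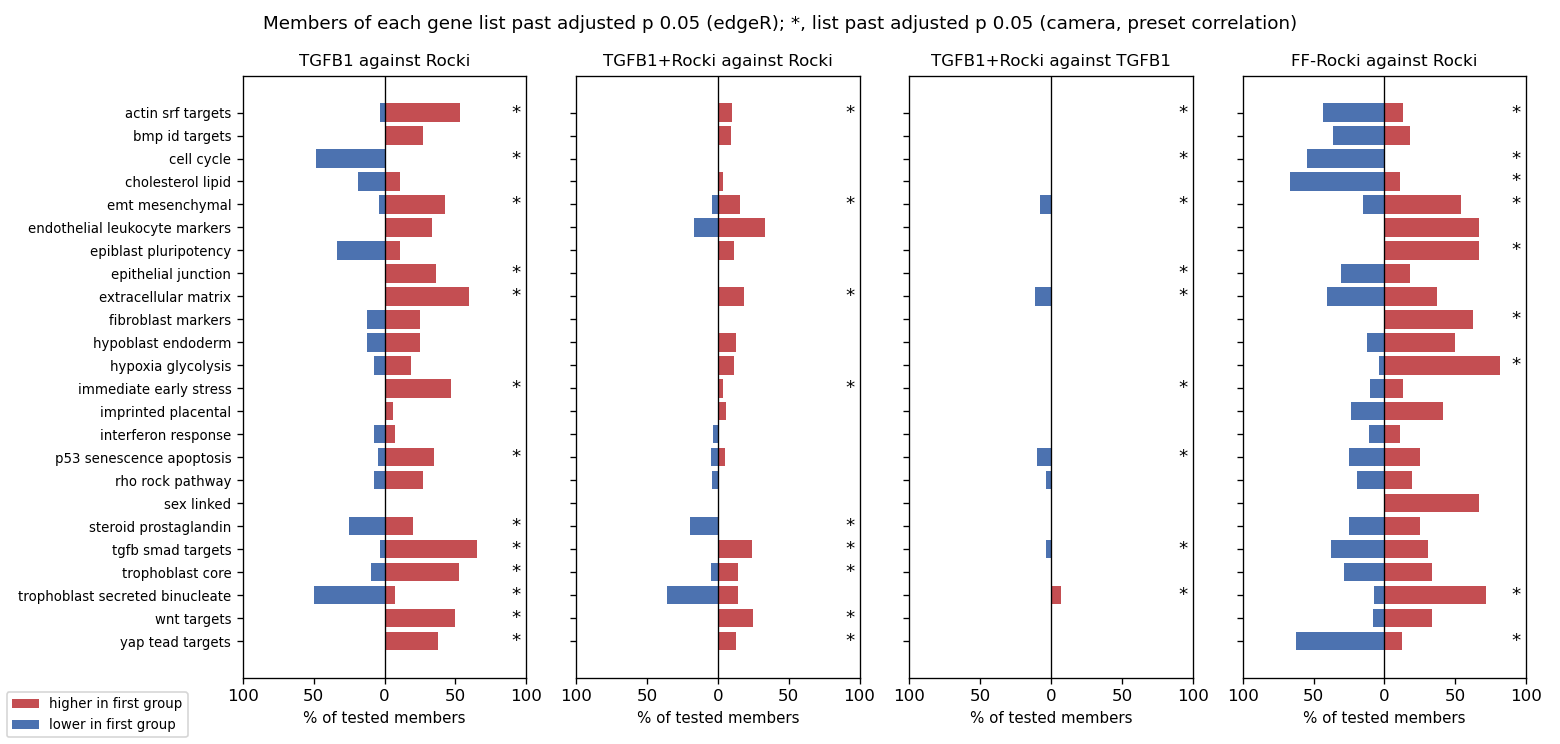
Percent of the tested members of each of 24 gene lists past adjusted p 0.05 in edgeR, higher (red) or lower (blue) in the first group, for the 4 comparisons; a star marks lists past adjusted p 0.05 in camera with the preset correlation. Extracellular matrix genes rose in TGFB1 against Rocki (16 of 27), and hypoxia and glycolysis genes in FF-Rocki against Rocki (22 of 27), and none of the 40 stars holds with an estimated correlation.

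FF-Rocki cells had more ADM and less HMGCS1 transcript than Rocki cells. ADM, the hypoxia-induced hormone adrenomedullin, was at 83.3 ± 43.7 against 2.73 ± 1.21 CPM (log2 fold change 4.93 ± 0.48, adjusted p = 1.3e-06). HMGCS1, an early enzyme of cholesterol synthesis, was at 118 ± 15.2 against 668 ± 176 CPM (-2.50 ± 0.19, adjusted p = 1.3e-07). Of 27 hypoxia and glycolysis genes 22 rose and 1 fell, or 23 and 1 adjusted over the list alone (camera adjusted p = 3.6e-09; adjusted p = 0.22 with an estimated correlation), among them GAPDH (1.12), PGAM1 (0.71) and BNIP3 (2.15). Of 27 cholesterol and lipid genes 18 fell and 3 rose, or 18 and 4 adjusted over the list alone (camera adjusted p = 4.2e-07; adjusted p = 0.21 with an estimated correlation), among them SQLE (-2.56), CYP51A1 (-1.91) and MSMO1 (-1.76). In all 3994 genes passed, 2084 higher and 1910 lower, and 1303 changed by at least 1 on the log2 scale (888 higher, 415 lower). The count was 2855 with the 2 groups alone and 3350 with limma-voom and a variance per group. The libraries did not overlap in 64.2% of the called genes and in 26.9% of all tested genes, where chance gives 1.59%. The coefficient of biological variation was 0.305 in FF-Rocki against 0.106 in Rocki. In data simulated with these spreads 32 of 185 called genes were unchanged ones. Only 67, 67 and 66 genes were changed there, by 1.5-, 2- and 4-fold, among 9471 tested. The real comparison had far more calls, so this share does not carry over to them, though more than 5% of them can still be false.

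Of the genes with increases in FF-Rocki against Rocki, 5 were named by fitted values though they had no count in Rocki. They are given as bounds against 3 counts per library, which cannot be ranked against genes counted in Rocki such as MMP14 (log2 fold change 8.70). DDX3Y, a gene of the Y chromosome, was at least 213-fold higher (34.3 ± 29.3 CPM), the interferon omega gene IFNW1 162-fold (26.1 ± 37.8 CPM), NRSN2 117-fold (18.9 ± 1.75 CPM), TMEM35 101-fold (16.3 ± 10.1 CPM) and CRP 89.0-fold (14.3 ± 1.84 CPM). The mean of DDX3Y rests on FF-Rocki 2, 3 and 4, at 47.1 to 68.3 CPM, against 0.103 in FF-Rocki 1 and 7.31 in FF-Rocki 5. The Rocki libraries had XIST at 458 to 670 CPM, so the DDX3Y bound follows sex-linked differences between libraries and not a rise across the group. The mean of IFNW1 rests on FF-Rocki 4, at 93.1 CPM against 1.21 to 14.8 CPM in the other FF-Rocki libraries. Whether these zeros in Rocki have the same origin as those of the abundant genes listed at 0 below was not tested, so the bounds hold only if the zeros are real. The 5 largest decreases among genes that met the naming rule were in KANK4 (log2 fold change -5.71), TDRKH (-4.50), IGFBP7 (-4.44), TAGLN (-3.72 ± 0.30, 14.3 ± 5.43 against 187 ± 74.8 CPM) and NTN4 (-3.68). KANK4 was at -6.62 without FF-Rocki 3 and IGFBP7 at -5.42 without FF-Rocki 5. Of 30 actin genes and SRF targets 13 fell and 4 rose, or 14 and 4 adjusted over the list alone (camera adjusted p = 0.018; adjusted p = 0.37 with an estimated correlation). CDC42EP3 (-2.42) and CALD1 (-1.26) fell, but ACTA2, smooth muscle actin, was at 48.8 ± 19.7 against 0.772 ± 0.0859 CPM (5.97 ± 0.36). Of 16 YAP and TEAD targets 10 fell and 2 rose, also when adjusted over the list alone (camera adjusted p = 0.0025; adjusted p = 0.27 with an estimated correlation), with CYR61 (-2.03), TGFB2 (-1.78) and CRIM1 (-1.64) lower and MYOF (0.87) higher. Of 33 cell cycle genes 18 fell, or 20 adjusted over the list alone (camera adjusted p = 1.8e-04; adjusted p = 0.27 with an estimated correlation), with KIF23 (-0.86), KIF20A (-0.73) and RRM2 (-0.86). The mesenchymal list had 14 of 26 higher and 4 lower, or 15 and 6 adjusted over the list alone (camera adjusted p = 0.018; adjusted p = 0.27 with an estimated correlation), with ITGB3 (3.80), ITGA5 (2.72) and MMP14 higher and THBS1 lower (146 ± 89.0 against 1169 ± 229 CPM), and VIM at 9.86 ± 2.05 against 12.3 ± 3.28 CPM (adjusted p = 0.21). The stress gene DDIT4 rose by 3.29.

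Of 9 epiblast and pluripotency genes 6 rose in FF-Rocki against Rocki, or 7 adjusted over the list alone (camera adjusted p = 5.5e-04; adjusted p = 0.21 with an estimated correlation), with FGF2 (log2 fold change 2.62), DPPA4 (3.41), LIN28A (2.07) and the glucose transporter SLC2A3 (1.15). Of 14 secreted and binucleate genes 10 rose and 1 fell, or 10 and 3 adjusted over the list alone (camera adjusted p = 0.026; adjusted p = 0.27 with an estimated correlation, and 0.074 with the 2 groups alone in the fit). The faller, TKDP1, was listed at 0 in FF-Rocki, and PAG11, listed at 0 in Rocki, was 1 of the risers. IFNT3 was at 2228 ± 3209 against 1.16 ± 0.469 CPM (10.89 ± 1.62, or 9.46 without FF-Rocki 4), and TKDP2 rose by 7.39 (8.35 without Rocki 3, 6.59 without FF-Rocki 5). PAG2 was at 7482 ± 2099.8 against 5621 ± 1221 CPM (adjusted p = 0.18). CDX2 rose by 1.49 ± 0.27 (adjusted p = 5.1e-04) and ELF5 by 1.55 (adjusted p = 0.0031), KRT8 (-0.51) and CDH1 (-0.38) fell, and GATA3 was at 232 ± 53.6 against 213 ± 30.6 CPM (adjusted p = 0.54). STAR, which moves cholesterol into mitochondria for steroid synthesis, rose by 4.83, or by 3.81 without FF-Rocki 5, which held 204 CPM against 18.0 to 58.5 CPM in FF-Rocki 1 to 4. Of 8 fibroblast markers 5 rose, or 7 adjusted over the list alone (camera adjusted p = 0.020; adjusted p = 0.32 with an estimated correlation). THY1 was at 77.4 ± 47.8 against 6.99 ± 2.2 CPM (3.47), LUM at 1.26 ± 0.894 against 0.0786 ± 0.068 CPM (3.88), and POSTN, with no count in Rocki, was at least 29.2-fold higher. In FF-Rocki 5 THY1 was at 8.63 CPM, within the Rocki levels, against 74.6 to 143 CPM in FF-Rocki 1 to 4, and POSTN at 0.999 against 3.87 to 7.33 CPM. SERPINE1 was at 556 ± 322 against 910 ± 69.5 CPM (adjusted p = 0.047), a call lost without any of the 4 Rocki libraries and without FF-Rocki 1, FF-Rocki 2, FF-Rocki 3 or FF-Rocki 4 (adjusted p up to 0.11), and SMAD7 at 6.44 ± 2.89 against 8.98 ± 0.619 CPM (adjusted p = 0.089, but 3.6e-05 without FF-Rocki 5, and under 0.05 in 2 further settings). The other 15 lists gave camera adjusted p from 0.064, for endothelial and leukocyte markers, to 0.85, for extracellular matrix, steroid and prostaglandin, and core trophoblast genes.

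The 5 FF-Rocki libraries differed among themselves. XIST, the RNA that coats the inactive X chromosome, was at 682 and 718 CPM in FF-Rocki 1 and FF-Rocki 5 and at 8.34, 6.89 and 6.63 CPM in FF-Rocki 2, 3 and 4, and did not pass between the groups (adjusted p = 0.49, but 0.0058 with limma-voom and a variance per group, 0.035 with the replicate block and 0.040 with limma-trend on FPKM). DDX3Y was at 48.9, 47.1 and 68.3 CPM in FF-Rocki 2, 3 and 4, at 7.31 CPM in FF-Rocki 5 and at 0.103 CPM in FF-Rocki 1, and had no count in the other 11 libraries. USP9Y, a further Y-linked gene, rose by 5.47. It was at 14.5 and 16.1 CPM in FF-Rocki 1 and FF-Rocki 5, at 40.8, 38.3 and 49.7 CPM in FF-Rocki 2, 3 and 4, and at 0.387 to 1.24 CPM in Rocki. IFNT3 was at 630, 1192, 1433 and 7884 CPM in FF-Rocki 1 to 4 and at 4.00 CPM in FF-Rocki 5, where CDX2 was at 11.8 CPM, within the Rocki levels. ELF5 was also within the Rocki levels in FF-Rocki 5, at 1.999 CPM, against 6.24 to 8.11 CPM in FF-Rocki 1 to 4. Without FF-Rocki 5 the count of genes against Rocki was 4824.

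**Figure D3:**
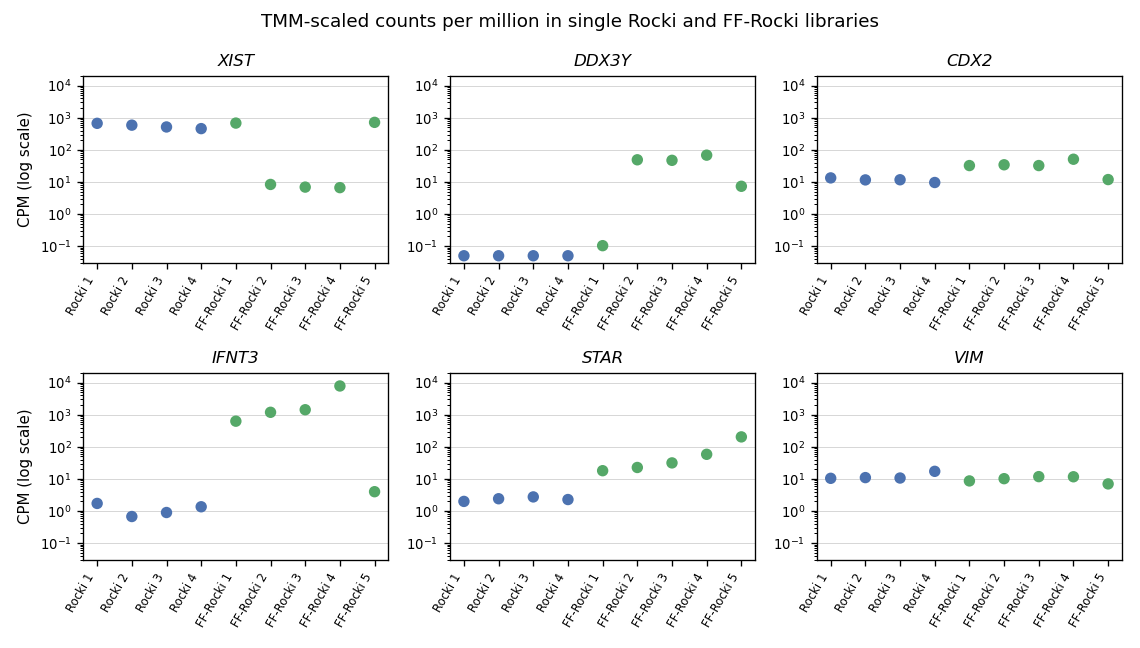
TMM-scaled counts-per-million of 6 genes on log axes in each Rocki (blue) and FF-Rocki (green) library, with values under 0.05 drawn at 0.05. XIST was under 10 CPM in FF-Rocki 2, 3 and 4, DDX3Y was at 0 in the Rocki libraries, and IFNT3 was at 4.00 CPM in FF-Rocki 5 against 630 to 7884 CPM in the others of its group.

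Some abundant genes were listed at 0 in every library of a group, so no fold change is given for them. EEF1A1, a translation elongation factor, was listed at 0 in all Rocki and FF-Rocki libraries and at 217594 to 273702 counts in the other 7. PAG11 was listed at 0 in Rocki and at 37344 to 248264 counts elsewhere. FN1, fibronectin, was listed at 0 in TGFB1 and TGFB1+Rocki and at 113108 to 178225 counts in Rocki and 5393 to 27788 in FF-Rocki. TKDP1 was listed at 0 in FF-Rocki and at 78352 to 138597 counts in Rocki. The ribosomal RNA genes RN18S1 and RN45S were listed at 0 in Rocki. Without these 6 genes in the fit the counts past the threshold were 2285, 358, 58 and 3977 for the 4 comparisons in the order given.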

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

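All tests of explanations in this part were chosen after the results they bear on were seen. The search for single outlying libraries was planned. The first forms of 2 tests, on genes at 0 and on a mixture in FF-Rocki 5, gave undecided outcomes and were replaced once these had been seen; both forms are given, and neither explanation is treated as settled. The test on sex of the embryos first used XIST alone and argued against sex; it was replaced after that outcome was seen, because of the USP9Y levels, and is treated as undecided.

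In 165 sets of 4 or 5 libraries, 1 per printed gene and group, 19 held a library far from the others of its group by Dixon's test at 95%, where chance gives about 1 in 20. In Rocki 4, CRCT1 was at 6.44 CPM (the others 3.20 to 3.37), RND1 at 5.67 (3.39 to 3.59), TAGLN at 299 (141 to 164) and VIM at 17.2 (10.4 to 10.997). In Rocki 3, COL12A1 was at 93.4 CPM (113 to 115) and SQLE at 51.9 (96.3 to 105), and in Rocki 1 LYZ3 was at 18.4 (4.75 to 5.89). In TGFB1 1, CDX2 was at 13.9 CPM (11.8 to 12.1), COL12A1 at 258 (172 to 184), ITGA5 at 148 (119.7 to 122) and PLAU at 882 (702 to 730.4), and in TGFB1 4 COL6A1 was at 3.23 (6.005 to 6.54). In FF-Rocki 5, DPPA4 was at 3.52 CPM (37.3 to 44.1), IGFBP7 at 13.2 (1.83 to 2.601), SMAD7 at 11.6 (4.56 to 5.56), STAR at 204 (18.0 to 58.5) and TKDP2 at 21.4 (3.71 to 5.36). In FF-Rocki 4, IFNT3 was at 7884 CPM (4.00 to 1433) and IFNW1 at 93.1 (1.21 to 14.8).

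Of the splits of the libraries fitted for 2 groups alone, only 1, the real one, gave as many genes in each comparison. A chance split of these libraries is thus unlikely, though 1 of 35 is the smallest share possible where there were 35 splits. For FF-Rocki against Rocki only 100 of 126 splits were fitted. A difference between cultures or embryos, which the labels do not give, cannot be excluded. The real count and the highest of the other splits were 4398 and 0 (35 splits) for TGFB1 against Rocki, 1314 and 350 (35) for TGFB1+Rocki against Rocki, 720 and 1 (35) for TGFB1+Rocki against TGFB1 and 2855 and 2582 (100 of 126) for FF-Rocki against Rocki. The split with 2582 placed FF-Rocki 5 with the 4 Rocki libraries, and the next had 964.

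Abundant genes were listed at 0 in whole groups in 8 cases, over 6 genes. The lowest of their highest counts was 3760.54, far above the floor of 3, which argues against too little depth. Means of the other elongation factor genes EEF1B2, EEF1G, EEF1D and EEF2 differed between groups by at most 1.82-fold, which argues against a loss of such transcripts as a class in Rocki and FF-Rocki cells, while a loss of EEF1A1 alone was not tested. Values lost in a step that was run group by group may account for the zeros, but this stays open: the first form of the test, any gene among the abundant ones at 0 in some libraries of a group only, found 1 case (CRCT1 in FF-Rocki, 3 libraries at 0 and the highest at 24 counts), and the second form, limited to cases with at least 100 counts in another library of the group, found 0.

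The genes that differ between FF-Rocki and Rocki could reflect several differences between the groups. Carry-over of bovine fibroblasts would bring VIM, an abundant fibroblast transcript, but its log2 fold change was -0.33 ± 0.20, with VIM at 6.995 to 11.8 CPM in the FF-Rocki libraries. Against this, 5 of 8 fibroblast markers rose. The collagen gene COL1A1 was at 21.4 to 38.1 CPM in FF-Rocki 1 to 4 and 6.68 in FF-Rocki 5, against 2.41 to 3.54 in Rocki, although of 27 matrix genes 10 rose and 11 fell. Carry-over thus stays open, and feeder cells of another species could not be tested. Sex of the embryos stays open: FF-Rocki 1 and FF-Rocki 5, with XIST at 682 and 718 CPM as in Rocki, lay beyond all Rocki libraries in 80.1% and 63.6% of the genes called without them, where chance gives 20%, but their Y-linked genes disagree: DDX3Y at 0.103 and OFD1Y at 0 CPM put FF-Rocki 1 with or near Rocki (both 0), USP9Y at 14.5 CPM was above its highest Rocki level of 1.24, and in FF-Rocki 5 all 3 were above Rocki (7.31, 1.89 and 16.1 CPM), so 0 of these libraries met the second form of the test. The 20% takes no account of the genes having been called against the same Rocki libraries, which can raise the share expected by chance. XIST was at 6.63 to 8.34 CPM and DDX3Y at 47.1 to 68.3 CPM in FF-Rocki 2, 3 and 4. In Rocki XIST was at 458 to 670 CPM and DDX3Y had no count, which argues against the same embryos for these 3 FF-Rocki libraries. How far different embryos account for the other genes cannot be told apart from the treatment, and the labels do not give the embryo. What FF stands for, including any effect of feeders, stays open as untested.

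FF-Rocki 5 stood apart from the other FF-Rocki libraries. As a Rocki library under the wrong label it would match Rocki, but it lay beyond all Rocki libraries in 63.6% of the genes called without it. Those genes were called against the same Rocki libraries, so a true Rocki library can lie beyond them in more than 20%. How far was not tested. A mixture of RNA like that of the other FF-Rocki libraries with RNA like that of the Rocki libraries could give intermediate levels, and DDX3Y at 7.31 CPM lay between the Rocki libraries (0) and FF-Rocki 2 to 4 (47.1 to 68.3), while XIST at 718 CPM did not lie between them. The first form of the test found 17 genes at least 3-fold above the other 8 libraries, against at most 7 in another FF-Rocki library and a bound of over 20; the second form found that of 77 genes 24.7% allowed only a share under 0.1 and 50.6% needed a share over 0.3, which no single share meets. Since the bound of the first was not reached and the second was devised afterwards, with ranges from 4 libraries that vary, a mixture remains open.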

How the results depend on the processing

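The fits without the FF-Rocki libraries, without the genes listed at 0 and with limma-voom and a variance per group were chosen after seeing the data; the others were planned.

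Against 2285, 378 and 59 genes for TGFB1 against Rocki, TGFB1+Rocki against Rocki and TGFB1+Rocki against TGFB1, the 2 groups alone gave 4398, 1314 and 720, the replicate block 3758, 1226 and 240, the fit without FF-Rocki 4260, 1932 and 892, and limma-voom 4627, 1388 and 589. Leaving the FF-Rocki libraries out of the fit thus raised each of these counts. The coefficient of biological variation was 0.305 in FF-Rocki against 0.106, 0.0796 and 0.124 in Rocki, TGFB1 and TGFB1+Rocki. The limma-voom fit kept the FF-Rocki libraries but gave each group its own variance. It also raised these 3 counts, and gave 3350 for FF-Rocki against Rocki, where the main fit gave 3994. Since limma-voom changes the test as well, whether this spread alone accounts for the moves stays open. A log2 fold change of at least 1 left 573, 153 and 36, and 1303 for FF-Rocki against Rocki, by construction. The DESeq2 Wald test gave 673 for TGFB1+Rocki against Rocki and 200 for TGFB1+Rocki against TGFB1, and the cause was not tested. Leaving out each library in turn gave 1447 to 2141, 100 to 416 and 10 to 38 genes, and 3261 to 4824 for FF-Rocki against Rocki, whose count otherwise stayed within 1.5 times 3994. Replicate numbers did not pair the libraries: correlations of deviations between libraries of the same number ran from -0.29 to 0.52, across genes. The replicate block values (3758, 1226, 240 and 5165) thus rest on an arbitrary pairing. The block also fitted FF-Rocki 5, the only library of its number, exactly. In effect it left that library out of the group differences.

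With library totals in place of TMM, 35.4% against 50.7% of the genes called in TGFB1 against Rocki were higher, and 43.5% against 54.8% in TGFB1+Rocki against Rocki; no scaling moved the median log2 fold change of all genes by more than 0.1. The reversed log2 fold changes were of genes not past the threshold: with library totals CDH1 (-0.020) and XIST (-0.062) in TGFB1 against Rocki and KRT8 (0.0097) in TGFB1+Rocki against TGFB1, and with the replicate block GATA3 (-0.014) in FF-Rocki against Rocki. With libraries left out, XIST in TGFB1 against Rocki ran from -0.072 to 0.11 and KRT8 in TGFB1+Rocki against TGFB1 from -0.083 to 0.047. The cause was not tested. Of the other log2 fold changes under alternatives, 3099 kept direction and side of the threshold, 140 lost the call (27 of these by the minimum log2 fold change of 1) and 39 gained one. Of the camera calls under alternatives 420 held and 51 did not, 40 of these with the estimated correlation.

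With 15407105 to 22709408 counts per library, 26.9% to 47.8% of 1.5-fold changes were recovered in simulated data, so changes of that size that were not called cannot be taken as absent.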

Other observations

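The genes in this part were chosen after their values were seen, and no difference between single libraries was tested.

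Among genes too rarely detected to be tested, several had counts in 1 or 2 FF-Rocki libraries. ABCG5, a sterol transporter gene, had 3657 counts in FF-Rocki 4 and 383 in FF-Rocki 3, and at most 4 in any other library. NPSR1 had 907 counts in FF-Rocki 4, and RNF182 had 657 in FF-Rocki 4 and 425 in FF-Rocki 2. In FF-Rocki 3 and FF-Rocki 5 the counts were 601 and 108 for SRGN, 500 and 189 for ESM1, 463 and 109 for the activin-binding follistatin gene FST, and 330 and 70 for the prolactin-related gene PRP6. FF-Rocki 3 also had 355 counts of FETUB and 316 of IGF2, and FF-Rocki 5 had 600 of the class II histocompatibility gene BLA-DQB and 315 of SBSN.

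Some tested genes peaked in 1 FF-Rocki library. FF-Rocki 3 had 80.2 CPM of SHISA2, 33.5 of SPARC and 16.5 of H19, against at most 17.8, 8.49 and 2.72 in the other Rocki and FF-Rocki libraries. FF-Rocki 5 had 79.6 CPM of IVL, 80.9 of LIPA, 38.1 of SERPINB2 and 36.5 of the imprinted gene CDKN1C, against at most 15.9, 23.3, 8.14 and 5.09 in the others. The Y-linked gene OFD1Y was at 14.5, 13.5, 10.8 and 1.89 CPM in FF-Rocki 2, 3, 4 and 5 and at 0 in FF-Rocki 1. HAND1, a trophoblast transcription factor, was at 456 CPM in FF-Rocki 5 and at 106 to 249 CPM in FF-Rocki 1 to 4.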
